A study of Homo sapiens with 4 samples.

How the data were processed

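The samples considered were an antibody library and an IgG library for palbociclib and for its control, with 1 library in each of 4 groups taken from the sample labels. Deposited values existed for the 2 antibody libraries only, as 1 list of peak regions each. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2, MACS2 2.1.0 and hg38, and give no parameters. Whether the IgG library served as the control of the peak caller is not given in the sources used here, and it was taken to be so because the background values behave as a second, smaller library. The deposited lists give, for each region, start, end and summit in bp. They also hold the authors' fold enrichment, a ratio of pileup over local background at the summit, the authors' unadjusted -log10 p and -log10 q, and a score. The authors' score is a whole number that follows the -log10 p. These peak values belong to each list and were used only to describe, rank or filter its regions and to recover fragments, and folds were not compared between lists. The smallest -log10 p of either list lay just above that of 0.05, from which an unadjusted cut-off of p at 0.05 was read.

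Fragments at a summit were recovered from the deposited ratio and -log10 p. The peak caller's fold is the pileup plus 1 over the background plus 1, and its p is the Poisson chance of more than the whole part of the pileup given the background. Both equations were solved together, with a pileup that is a whole number of fragments times 1 scale per list (tolerance 0.01 of a fragment) and a background on the grid of IgG fragments (tolerance 0.05%). One scaled unit held 19.3 fragments in the palbociclib-labelled list and 42.1 in the control-labelled list. A solution was found for 99.99% of regions in both lists, none for 13 and 6, and several for 485 and 75, where the lowest background was taken. The mean distance from a whole fragment was 6.27e-05 and 9.98e-05. Mean coverage of the antibody libraries followed as 0.439 and 0.437 fragments per base, and the fragment length as 93.2 and 99.2 bp. With 1 genome size for both, this gives 2.33 times as many IgG fragments, and 1.07 times as many antibody fragments, behind the palbociclib-labelled list. The counts carry no molecular identifiers, so intervals cover counting error only.

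The gene lists, the planned comparisons and their alternatives, and the rule for named genes were fixed before the data were examined. That rule names the 10 genes with a region in 1 list only that rank highest by q, then fold, with no region of the other list within 5 kb, counting genes that share a region as 1. It adds the 6 best shared genes by the worse of their ranks, here by fragments, a change made after the data were examined since q was 1 at most regions. It also takes CGAS, STING1, TBK1, IRF3, RB1, CDK4, CDK6, E2F1 and CDKN1A whatever they show, and up to 4 members per list with a region in 1 list only. Genes and gene ends came from the RefSeq table at hand, which gives no strand, no transcript starts and no sequence. Promoters were therefore replaced by windows of 1 kb either side of both ends of 20033 protein-coding genes on chromosomes 1 to 22, X and Y. Motif searches, matching on CpG content and classes of exon, intron and UTR were planned and could not be run. The planned overlap used 1 bp or more, exact Clopper-Pearson 95% intervals and 100 shuffles of regions along their chromosomes.

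The comparison of fragments was chosen after the data were examined, because the deposited lists cover most of the genome. A strong summit had 20 or more fragments. Sites were windows of 200 bp either side of strong summits, taken from the highest down over both lists. A site counted for both libraries when regions of the other list covered the whole window and their highest summit lay in it. Its ratio needed 40 or more fragments over both, was divided by the coverage ratio of 1.01, and has an exact binomial 95% interval. A gene was below a strong summit when regions covered both of its end windows and all their summits had under 20 fragments, and open when the lists did not decide. Medians have bootstrap intervals of 2000 draws over sites, or 1000 for the alternatives. Sites 2-fold or more from the median ratio were set against 1000 binomial draws around it. Of sites 2-fold or more from the median, those with the interval bound nearest to 1 lying farthest from it were named, at gene ends and elsewhere. Members given as examples of lists with strong summits were also chosen after their values were seen. The 19 gene lists were set against 10000 random lists of equal size, and their ratios (lists with 3 or more members) against random genes from the same 1 of 10 classes of fragments. These percentiles describe the libraries and are not tests between conditions.

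The steps were tested on simulated data. Fragments were right in 100% of 18972 and 19045 simulated regions. These were made with the formulas, background grid and single scale that the recovery assumes. The result therefore checks the solving of the equations, and not whether the deposited lists follow them. With 3-fold changes planted at sites, 96.4% of 197 raised and 93.8% of 195 lowered sites were found, 0.896% of 3347 unchanged sites were called, and a true ratio of 1.2 came out as 1.21. Each simulated site had its own region in both lists with summits close together, and only paired sites were counted. These rates therefore leave out losses at pairing, where 5069 of 9070 sites of the data were paired. Planted lists reached the 99.98 and 100 percentiles, and 6 and 4 of 100 lists with nothing planted fell outside the central 95%. Alternatives changed the thresholds of q, fold and fragments, the overlap rule, the windows, the chromosomes and the number of regions. Regions on other contigs were left out of all comparisons, since genes there repeat those of the main chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a random seed of 7.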

Results

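The series asked how CDK4 and CDK6, the kinases that drive cells into S phase, restrain signalling through STING, the adaptor that answers DNA in the cytosol, and what part the retinoblastoma protein RB1 takes in it. Chromatin was profiled in 22RV1 cells, a human prostate carcinoma line, with palbociclib, an inhibitor of both kinases, and in its control. There were 4 samples in 4 groups, 1 antibody library and 1 non-specific IgG library per condition. The labels call the assay CUT&Tag, although the protocol they give fixes and sonicates chromatin. The antibody's target is not given in the sources used here. Lists of peak regions on hg38 were at hand for the 2 antibody libraries, and the IgG libraries had no file of their own. With 1 library per group, no test between conditions was possible, and each comparison below is between libraries. The peak names disagreed with the sample labels. All names in the palbociclib sample's list carried the control's code, all names in the control's list carried the drug's code, and both named 786-O, a renal carcinoma line. The libraries are therefore called palbociclib-labelled and control-labelled, and every direction below holds for those labels only.

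The palbociclib-labelled list held 126410 regions and the control-labelled list 61470. The regions covered 2.63 and 2.83 Gb of the genome, so either list took in most of it. The peak caller's q, the authors' own value for a region, was 1 in 97.8% and 99.8% of regions and under 0.05 in 959 and 25. The fold and p of a region fix the number of antibody fragments at its summit, and these whole numbers were recovered for all but 13 and 6 regions. The median region had 4 and 5 fragments at its summit, and the highest had 435 and 407. Mean antibody coverage was close in the libraries, 0.439 and 0.437 fragments per base. The IgG background was not: it was 2.19 times higher behind the palbociclib-labelled list. All intervals below are 95% intervals that cover counting error only.

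Taken as deposited, the lists placed a region at nearly all genes, those of the STING pathway included. All 20 members of the cGAS-STING list, the cytosolic DNA sensor, its adaptor and their partners, had a region within 1 kb of a gene end in both lists, as did all 28 interferon-stimulated genes and all 20 mitotic genes. CDKN2D, an inhibitor of CDK4 and CDK6, had a region in the palbociclib-labelled list only, with 40 fragments at the summit. In the control-labelled list only were SLC45A3, an androgen-regulated prostate gene (35 fragments), TNFRSF10B, a death receptor induced by p53 (28), and RRM1, a subunit of ribonucleotide reductase (17). HOXB8, a homeobox gene (12), IL6, an inflammatory cytokine (11), and HLA-C, which presents peptides to T cells (9), were also in that list only. Replication-dependent histone genes were split, with 7 in the palbociclib-labelled list only, led by H3C13 (22), H2AC13, H2BC13 and H3C10 (21 in 1 region), and 2 in the control-labelled list only, H4C11 (16) and H4C4 (13). Of the olfactory receptor genes, which serve the sense of smell, 5 were in the palbociclib-labelled list only, led by OR2C1 (54), OR2T5 (8), OR11L1 and OR2M5 (5). In the control-labelled list only were 12, led by OR4D11 (20), OR2B11 (13), OR5W2 (8) and OR5H2 (9). Regions were wide, with medians of 13374 and 29223.5 bp, and a region's summit could lie far from the gene it reached. A gene without a region in a list stayed open there, since its fragments in that library are then not known.

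Over 20033 protein-coding genes, 19641 had a region within 1 kb of a gene end in the palbociclib-labelled list, 19875 in the control-labelled list and 19530 in both. This left 111 genes with one in the palbociclib-labelled list only and 345 in the control-labelled list only. These genes too stayed open in the list without a region. When a region within 5 kb in the other list also ruled a gene out, 11 and 53 were left, none of them with a q under 1. The 11 were led by ARRDC1, with 45 fragments at the summit of its region, GGTA1 with 32, C8orf33 with 29, RASSF7 with 26, UTS2R with 18, CYSRT1 with 22 and LOC124901638 with 13. LOC102723407, LOC124905463, LOC124905466 and BAGE5 followed with 1 fragment each, in regions that span the short arms of chromosomes 13 and 14. The 53 were led by the pair LOC124901647 and LOC124901652 with 30 fragments, then RPLP1, a protein of the ribosomal stalk, SLC12A3, a renal sodium chloride transporter, and HDAC10, a deacetylase, with 26 each. FAM90A24 followed with 21, TAF11L6 with 19, LOC102724813 and TREX2, an exonuclease, with 16, and LOC124900573 and the pair FAM90A8 and FAM90A16 with 13. Regions of the palbociclib-labelled list overlapped 96.0% of control-labelled regions (95.9 to 96.2), against 96.8% when these were shuffled along their chromosomes. In the other direction the share was 98.2% (98.2 to 98.3), against 96.5% shuffled. The counts of genes in 1 list only rest on the regions taken: they were 419 and 5 at a fold of 5 or more, a fold that by its scaling to IgG asks for more fragments in the control-labelled list, and with the same number of regions from each list 1560 genes were in the control-labelled list only. Under a reciprocal overlap of 50%, the shares overlapped were 30.2% and 14.6%, from 17855 regions in either list.

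Regions with many fragments lay at genes. The highest gene-end summit in both libraries stood 507 bp from an end of FARP2, an exchange factor for small GTPases, on chromosome 2 at 241355778. Of summits with 20 or more fragments, called strong here, 63.4% (62.3 to 64.4; 5080 of 8017) lay within 1 kb of an end of a protein-coding gene in the palbociclib-labelled library. In the control-labelled library the share was 67.9% (66.6 to 69.2; 3544 of 5218), and 2.36% of the genome lies that near. Among summits with 1 to 4 fragments the shares were 1.60% and 1.88%, and among those with 10 to 19 they were 34.2% and 40.9%. At 100 or more fragments the shares were lower than at 43 to 99, with 50% (42.8 to 57.2) against 67.6% (65.7 to 69.5) in the palbociclib-labelled library. The annotation at hand gives no strand, so the start of a gene could not be told from its end.

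**Figure D1:**
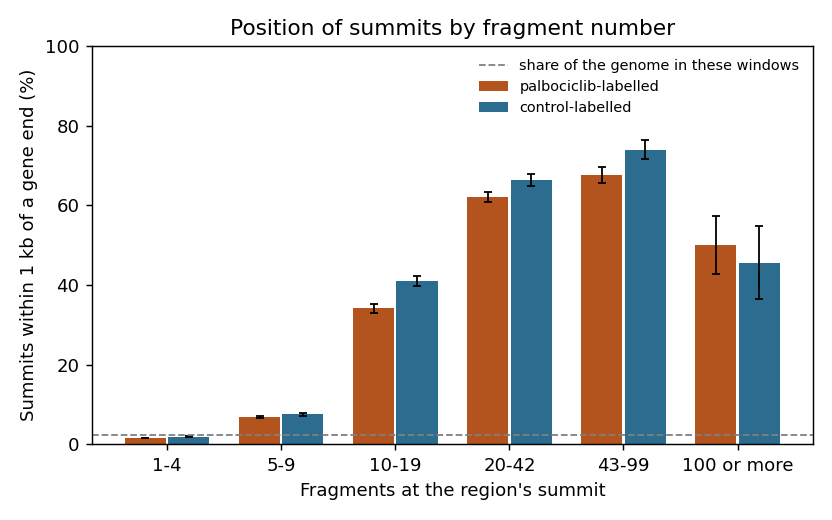
Share of summits within 1 kb of a protein-coding gene end (percent, vertical axis) by fragments at the summit (horizontal axis), in each antibody library; error bars are exact 95% intervals and the dashed line is the share of the genome that lies that near. Shares rose from 1.60% and 1.88% in the lowest class to 67.6% and 74.0% at 43 to 99 fragments.

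The 6 best shared gene-end sites had ratios from 0.93 at TMEM87B to 1.59 at ZNF595, and the intervals of 3 of them, ZNF595, SPATC1L and EEPD1, lay above 1. At FARP2, 435 fragments in the palbociclib-labelled library stood against 407 in the control-labelled library, a ratio of 1.06 (0.93 to 1.22) after division by the coverage ratio of 1.01. ZNF595, a zinc-finger gene, had 322 against 201 (ratio 1.59, 1.33 to 1.91), and EEPD1, which takes part in the repair of stalled replication forks, 247 against 185 (1.33, 1.09 to 1.62). The interval of EEPD1 includes the median ratio of all paired sites, 1.21. SPATC1L had 288 against 183 (1.57, 1.3 to 1.89), TMEM87B 214 against 229 and BRD3OS 205 against 169. A summit between FAM228B and TP53I3, a p53 target, had 170 against 158, and one beside CYCS, the gene of cytochrome c, 161 against 137. Inside PEG10, an imprinted gene, 335 stood against 317. FAM228B, CYCS and PEG10 are outside the naming rule and were picked after their values were seen.

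Strong summits of either library made 9070 sites of 200 bp either side. In 5069 of these, 3383 at a gene end, both libraries had their summit in the site. That was so for 62.7% (61.6 to 63.7) of strong palbociclib-labelled sites and 78.7% (77.6 to 79.8) of strong control-labelled ones. In 1629 and 433 sites the highest summit of the other list lay elsewhere and only bounds its level. These shares therefore do not measure signal alone. Of the 5069, 4418 had 40 or more fragments over both libraries and were given a ratio. The median ratio of palbociclib-labelled to control-labelled fragments was 1.21, 0.28 on the log2 scale (0.26 to 0.29, bootstrap over sites), and 79.6% of sites lay above a ratio of 1. The log2 ratios had an SD of 0.36, and counting alone gives 0.36. At gene ends the SD was 0.33 against 0.35 from counting, and elsewhere 0.41 against 0.37. Pairing leaves out sites whose summit in the other list lies elsewhere, which can narrow these spreads. Sites at gene ends had a median log2 ratio of 0.25 (n = 3045) and sites elsewhere one of 0.36 (n = 1373). The difference was 0.12 (0.07 to 0.14), or 0.08 (0.03 to 0.11) with 80 or more fragments over both libraries. Sites are not replicates, and these values describe a pair of libraries.

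**Figure D2:**
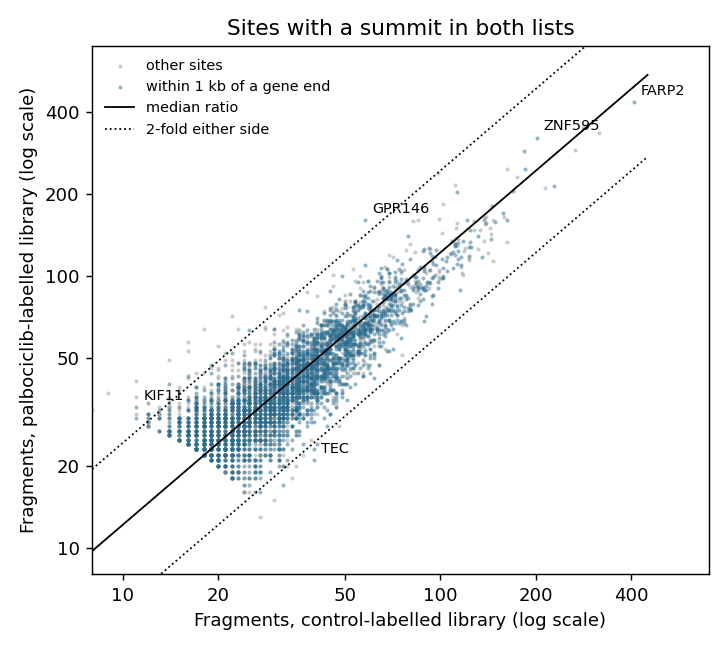
Fragments at the summit in the palbociclib-labelled library (vertical axis, log scale) against the control-labelled library (horizontal axis, log scale) for the 4418 paired sites; the solid line is the median ratio of 1.21 and the dotted lines lie 2-fold either side of it. Of the sites, 39 lie on or above the upper dotted line, KIF11 with 33 and 11 fragments and GPR146 with 160 and 58 among them, and 12 on or below the lower one.

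Few of the paired sites stood apart from that median. Among those at gene ends, GPR146 had the interval farthest from 1. This gene of an orphan receptor, which lies within CHLSN on chromosome 7, had 160 fragments in the palbociclib-labelled library against 58, a ratio of 2.74 (2.02 to 3.77). KIF11, the kinesin that separates spindle poles, had 33 against 11 (2.98, 1.47 to 6.54). PCDH20, a protocadherin, had 63 against 25 (2.51, 1.55 to 4.16). EXOSC3, a subunit of the RNA exosome, had 43 against 16, and FASTKD3, which acts on mitochondrial RNA, 40 against 14. ZNF292, a zinc-finger gene, had 47 against 19. Away from gene ends, USP10, a deubiquitinase, held a site of 64 against 18 (3.54, 2.07 to 6.34), JAKMIP3 one of 57 against 16 and LOC124900165 one of 71 against 22. A site nearest to RBMX, an RNA-binding protein, had 37 against 9. PRKAR1B, a regulatory subunit of protein kinase A, held one of 239 against 98 (2.43, 1.91 to 3.10) and GTF2IRD1 one of 49 against 14.

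On the other side, TEC, a tyrosine kinase of blood cells, had 40 fragments in the control-labelled library against 21, 1.92 times as many (1.1 to 3.42). BTAF1, which removes the TATA-binding protein from DNA, had 32 against 17, VRK3, a kinase-like protein, 40 against 23, and SPIN1, a reader of histone marks, 41 against 24. Away from gene ends, the site nearest to CFAP46 had 48 against 28, and that nearest to TGFA, a ligand of the EGF receptor, 30 against 15. In all, 39 of the 4418 sites lay 2-fold or more above the median ratio, 11 of them at gene ends, and 12 lay 2-fold or more below it, 5 at gene ends. Counting alone around the median gave 24.4 on average (95% of draws between 15 and 34) and 18.7 (11 to 27) in 1000 simulated draws. These draws held no pairing step and were not split by position. The spread of the data was under that of counting at gene ends and over it elsewhere. The draws therefore cannot show whether counting accounts for the 39 and 12 sites. The sites named are among these, taken in the order of the interval bound nearest to 1 with those under 2-fold passed over, a rule chosen after the data were seen. Where the summit of the other list lay outside the site and only bounds its value, 8 more sites were 2-fold or more above the median, such as IQSEC3 with 33 against at most 10, and 3 were as far below it. Sites that the other list did not fully cover, 1299 and 640, could not be compared. With 80 or more fragments required over both libraries, 7 and 0 sites were left, and from 10 fragments per summit (20 over both) there were 136 and 77.

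E2F targets, mitotic genes, DNA repair genes and p53 targets had strong summits, of 20 or more fragments, more often than random lists. With strong summits set at 43 fragments, p53 targets alone of these stayed in the top 2.5% (percentile 99.8). E2F targets then lay at 33.1 with 2 of 26 members, DNA repair genes at 73.3 and mitotic genes at 96.4. Of 20033 genes, 5962 had a strong summit within 1 kb of an end in the palbociclib-labelled library, 4263 in the control-labelled library and 3729 in both. Of those with one in the palbociclib-labelled library only, 603 stayed below a strong summit in the other library and 1630 stayed open there. The other way, 74 stayed below and 460 open. Most genes with a strong summit in 1 library only were therefore undecided, since the lists do not settle the level of open genes in the other library. Genes that stayed below had under 20 fragments there, which by itself does not show a difference in signal. Values below are for the strongest summit near either end of a gene, palbociclib-labelled first. E2F targets of S phase had one in either library in 18 of 26 members, a count at the 99.995 percentile of 10000 random lists of the same size. PCNA, the sliding clamp of replication, had 85 fragments against 77, TK1 41 against 48, MCM2 31 against 36 and EZH2 40 against 28. Mitotic genes had one in 14 of 20 (percentile 99.98), with NEK2 at 76 against 45, UBE2C at 57 against 33, TTK at 53 against 53 and AURKA at 49 against 53. DNA repair genes had one in 13 of 20 (percentile 99.8), with BARD1 at 107 against 102 and ATM at 84 against 72. So did 13 of 20 p53 targets (percentile 99.8), with RRM2B at 98 against 101, GADD45A at 66 against 54 and XPC at 44 against 60. The CDK4/6-RB list had one in 10 of 18 members (percentile 97.9), and no longer lay in the top 2.5% of random lists with strong summits set at 10 or 43 fragments or with windows of 500 bp.

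Interferon-stimulated genes, antigen presentation genes, secreted factors of senescence, HOX genes and olfactory receptors had listed strong summits less often than random lists. Open members, whose ends the lists did not cover or bound in at least 1 library, numbered 19 of 28, 15 of 20, 13 of 19, 27 of 39 and 149 of 392, and count as having none where neither library lists one. Interferon-stimulated genes had a strong summit in 3 of 28 members (percentile 0.61), among them STAT2 with 42 against 41 and IRF1 with 45 against 50. The summits at IRF1 did not form a paired site. Antigen presentation genes had one in 2 of 20 (percentile 1.19), one of them CALR with 37 against 40, and senescence-associated secreted factors in 1 of 19 (percentile 0.31), IGFBP3 with 37 in the palbociclib-labelled library. HOX genes had one in 4 of 39 (percentile 0.065), among them HOXC13 with 42 against 41, and olfactory receptors in 0 of 392. Markers of fibroblasts, leukocytes and endothelium had none in 10 members each (percentiles 1.14, 0.93 and 0.92). Between these lay ribosomal proteins with 8 of 20 (percentile 76.5), the androgen receptor programme with 7 of 20 (60.4) and NF-kB genes with 6 of 21 (37.4). The neuroendocrine list had 4 of 15 (33.0) and replication-dependent histones 16 of 69 (4.62). From 10 fragments, ribosomal proteins lay at 99.1, in the top 2.5%, NF-kB genes at 90.8 and histones at 70.96. Random lists were drawn from all protein-coding genes with no matching on CpG content, since no genome sequence was at hand. Members of lists with neighbouring genes, such as the HOX and histone lists, can share a region and its summit. Random lists did not match this, so the percentiles of such lists may overstate how unusual their counts were. At 43 fragments the 3 lists in the bottom 2.5% were replication-dependent histones (percentile 0.955), HOX genes (0.50) and olfactory receptors (0), and interferon-stimulated genes lay at 10.9, antigen presentation genes at 22.7 and secreted factors at 5.58. Antigen presentation genes left the bottom 2.5% under every alternative tried, at 6.83 from 10 fragments, 2.59 within 500 bp and 20.4 within 5 kb. Within 5 kb the secreted factors (5.19) and the markers of fibroblasts (11.1), leukocytes (11.1) and endothelium (2.91) left it too, and histones (1.97) entered it. At 43 fragments the markers lay at 15.7 to 15.9.

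**Figure D3:**
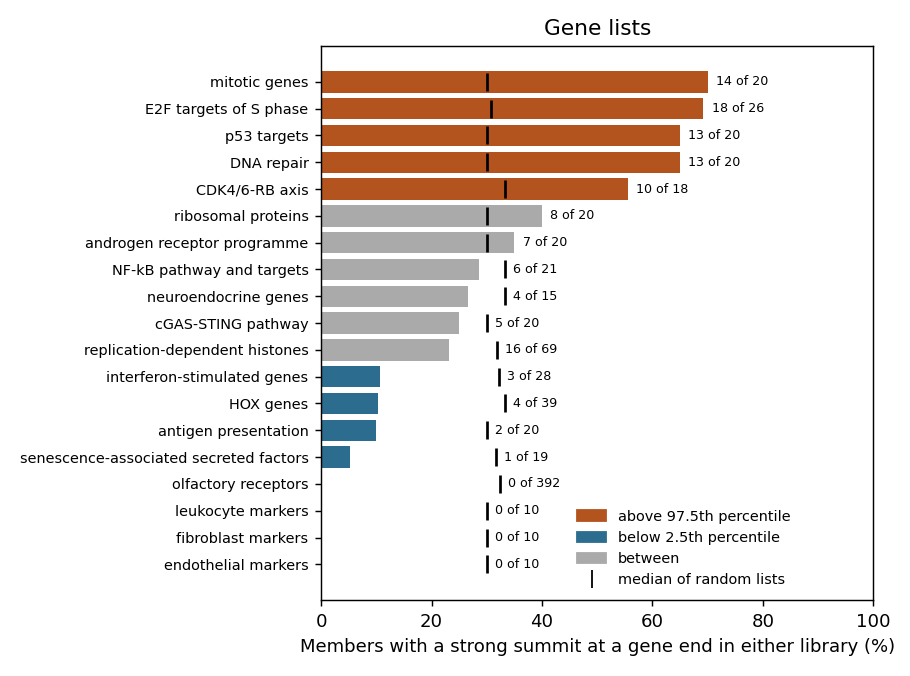
Members of each gene list with a strong summit at a gene end in either library (percent, horizontal axis); black marks give the median of 10000 random lists and the figures beside the bars give the counts. Mitotic genes (14 of 20) and E2F targets (18 of 26) lie highest, and the cell type markers and olfactory receptors (0 of 392) lowest.

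Few genes of the STING pathway could be compared, since 3 of 20 had a ratio of the libraries. Of the cGAS-STING list, 5 of 20 members had a strong summit (percentile 24.9), and 13 stayed open in at least 1 library because the lists did not cover or bound their ends. TBK1, the kinase that STING recruits, had 40 fragments in the palbociclib-labelled library against 49 (ratio 0.81, 0.52 to 1.26). DDX41, a DNA-sensing helicase, had 38 against 34 (1.11, 0.68 to 1.82), and SAMHD1, which degrades dNTPs, 39 against 30 (1.29, 0.78 to 2.16). TREX1, the exonuclease that clears cytosolic DNA, had 38 in the palbociclib-labelled library, and IRF7, an interferon regulator, 20 in the control-labelled library. Both stayed open in the other library, so neither value shows a difference between the libraries. CGAS, the sensor itself, stayed below a strong summit in both, with at most 6 and 8. STING1 stayed below one in the palbociclib-labelled library with at most 5 and could not be bounded in the control-labelled library. For IRF3, which TBK1 activates, no strong summit was listed near an end, and regions reaching beyond its ends had higher summits elsewhere, so its level stayed open.

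Among the drug's own targets, CDK4 had 102 fragments against 64, a ratio of 1.59 (1.15 to 2.20) that includes the median of all sites, 1.21. CDK6 had no strong summit listed near its ends and stayed open. CDKN2B and CDKN2C, inhibitors of both kinases, had 56 against 54 (1.03, 0.70 to 1.53) and 52 against 36 (1.44, 0.92 to 2.26). E2F3, a transcription factor held by RB1, had 62 against 50, and E2F1 had 26 in the palbociclib-labelled library and stayed open in the other. RB1 stayed below a strong summit in the palbociclib-labelled library, with at most 10 fragments, and CDKN1A, the p53-induced inhibitor p21, did so in the control-labelled library, with at most 19. Both stayed open in the other library.

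The ratio of the libraries was set against random genes matched on fragments for the 9 lists with 3 or more members that had one. The cGAS-STING list had a median log2 ratio of 0.15 (n = 3, percentile 38.2), E2F targets 0.31 (n = 9, 67.7), the CDK4/6-RB list 0.32 (n = 6, 77.5) and DNA repair genes 0.21 (n = 11, 39.5). The medians of mitotic genes (0.14, n = 10, 14.6), p53 targets (0.08, n = 8, 11), the androgen receptor programme (0.13, n = 6, 18.4) and NF-kB genes (0.28, n = 5, 53.1) also lay within the central 95% of random lists. Ribosomal protein genes lay at the 2.26 percentile with a median of -0.15, from 3 genes only. These were RPL5 with 31 fragments against 32, RPLP0 with 27 against 35 and RPL27 with 29 against 32, none with an interval that excludes a ratio of 1. On simulated data 4 of 100 lists with nothing planted fell outside that range, and 9 lists were looked at here. NFKBIA, the inhibitor of NF-kB, had 30 against 15 (ratio 1.99, 1.04 to 3.98), and C1orf116, an androgen-regulated gene, 107 against 65 (1.64, 1.19 to 2.26). Both intervals include the median of all sites, 1.21.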

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

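All tests in this part were chosen after the results had been seen.

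In the palbociclib-labelled list 100% of peak names, and in the control-labelled list 100%, name the other condition and 786-O, a signal in a column that no comparison used. A line with CDKN2A deleted, as 786-O is known to be, should leave no fragments in that gene. The highest summit inside CDKN2A had 6 fragments in the palbociclib-labelled library, on chromosome 9 at 21970924, and the control-labelled list had 1 region across the gene with its summit outside. A few misplaced reads could give 6 fragments, and the neighbouring CDKN2B had 56 and 54, but how far the deletion reaches is not given in the sources used here, so the line cannot be told apart by this test. A swap of conditions might lower E2F target sites in the control-labelled library if the antibody followed E2F activity, but their ratios lay at the 67.7 percentile of random lists and the target is unknown, so a swap cannot be told apart either.

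Summits of 20 or more fragments also lay on contigs outside the main chromosomes, which were left out of the comparisons: 248 in the palbociclib-labelled list and 127 in the control-labelled list.

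The palbociclib-labelled list holds 2.06 times as many regions as the control-labelled list. A deeper antibody library is argued against by a coverage ratio of 1.01 and a ratio of inferred antibody fragments of 1.07. Regions with a scaled pileup of 1 or more, 19.3 fragments in that list, come to 12.7% of the excess even when all are counted. Enrichment of that height at more places therefore does not account for the excess, and weaker enrichment is not counted by this test. On the main chromosomes strong summits numbered 8017 and 5218. Summits with 1 to 4 fragments numbered 79361 and 27965, and 1.60% and 1.88% of them lay at gene ends, against 2.36% of the genome. A deeper IgG library, at 2.33 times the inferred fragments, goes with the longer list and stays as a candidate explanation. Weaker enrichment at more places stays open.

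Summits were higher in the palbociclib-labelled library, by 1.22 times before division by coverage (1.21 to 1.23). A deeper antibody library alone is argued against, since coverage differed by 1.01 times and inferred antibody fragments by 1.07 times, both under 1.21. Ratios were divided by the coverage ratio, and division by 1.07 would lower them. A change at a minority of genes is argued against by 79.6% of sites with a ratio above 1. The spread of log2 ratios was 1.01 times what counting gives over all sites, but 0.33 against 0.35 at gene ends, less than counting alone can give, so pairing may narrow it and it does not decide whether the difference was of the whole library. That explanation stays open, and so does whether it came from the efficiency of the antibody step or from more binding in the cells, and which condition the library came from, with 1 library per condition.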

How the results depend on the processing

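Of 103 alternatives, 60 were planned and 43 were chosen after seeing the data. A value stayed within its interval, or a count within 1.5 times, in 37 (16 planned), 66 moved and 0 changed sign. Only the median log2 ratio and its difference between other sites and gene ends have a sign, so counts and shares could not change it. The order of the libraries did turn round, which for q and fold follows from their construction: both are scaled to IgG depth, with 19.3 and 42.1 fragments per unit, so equal thresholds are stricter in the control-labelled list. That is, genes in 1 list only were fewer on the palbociclib-labelled side as reported and more at either -log10 q or at a fold of 5 or more, as were gene list members at a -log10 q of 5 or more. The share overlapped was lower for control-labelled regions as reported and higher under those thresholds and under both other overlap rules. In these settings both shares count the same or nearly the same number of regions, so the lengths of the lists fix that order. Reciprocal overlap counted 17855 in either list, and summits within 200 bp 13034 and 13042, control-labelled first. The palbociclib-labelled share of regions at gene ends was the lower one as reported and the higher one at a fold of 5 or more and with equal numbers. For values that moved, the cause was not tested unless given. The 3 motif alternatives, random lists matched on CpG content, transcript start windows and shuffling among promoters were not run, for want of sequence and strand. No paired analysis was possible because each group has 1 library.

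Values are given palbociclib-labelled first, in the order regions, share of control-labelled and of palbociclib-labelled regions overlapped, genes in 1 list only, and share of regions at gene ends. At a -log10 q of 5 or more, where few regions are left by construction, they were 300 and 5, 100% and 1.67%, 401 and 4, and 60% and 80%. At 10 or more they were 42 and 2, 100% and 4.76%, 28 and 2, and 38.1% and 50%. At a fold of 5 or more they were 344 and 10, 90% and 2.62%, 419 and 5, and 58.7% and 50%. With equal numbers of regions (59168) the shares overlapped were 80.1% and 99.1%, 1560 genes were in the control-labelled list only, and 16.3% of palbociclib-labelled regions lay at gene ends. A q under 0.05 left 959 and 25 regions.

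With a reciprocal overlap of 50% the shares overlapped were 30.2% and 14.6%, and with summits within 200 bp 22.0% and 10.7%. Windows of 500 bp put 7.0% and 11.3% of regions at gene ends, and windows of 5 kb, wider by construction, 15.9% and 20.1%, with 12 and 62 genes in 1 list only. Members of the gene lists in 1 list only, 13 and 20 as reported, were 0 and 3 with 5 kb, 5 and 0 at a -log10 q of 5 or more, and 164 in the control-labelled list with equal numbers.

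Sites 2-fold from the median were 136 and 77 from 10 fragments (20 over both), 14 and 1 from 43, and 7 and 0 with 80 over both. The median log2 ratio was 0.29 from 43 fragments and 0.25 with 80 over both. Strong summits at gene ends made 50.05% and 53.9% from 10 fragments, 66.2% and 71.7% from 43, 58.3% and 63.3% within 500 bp, and 72.9% and 76.1% within 5 kb. With equal numbers of summits the palbociclib-labelled share was 66.9%. From 43 fragments 1 gene list lay above and 3 below random lists, and within 5 kb 4 lay below. The depth of 40 fragments per site limits ratios to differences of about 2-fold.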

Other observations

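Strong summits were found at 16 of 69 replication-dependent histone genes, which are transcribed in S phase. H2AC25 and H2BC26, neighbours with the same values, had 48 fragments at the strongest summit in the palbociclib-labelled library and 21 in the control-labelled library. H2AC18 and H3C14 had 37 and 38. The summits of these 4 genes did not form paired sites, so they have no ratio and the values do not compare 1 place. H2AC11 and H2BC11 had 31 and 36 at a paired site. Neuroendocrine genes included POU3F2, a neural transcription factor, with 38 fragments against 28 (ratio 1.35, 0.81 to 2.28). In the androgen receptor programme ELL2, an elongation factor, had 68 against 46 (1.47, 1.00 to 2.19).

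On contigs outside the main chromosomes there were 4477 regions in the palbociclib-labelled list and 2302 in the control-labelled list. Of these, 3807 and 1890 lay on alternate contigs. The highest summits, with 361 and 274 fragments, stood on an unlocalized contig of chromosome 14 in both lists.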
